A study of Mus musculus with 2 samples.

How the data were processed

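The data are gene and transcript tables for 2 libraries of total RNA from forebrain of B6NCrl mouse embryos at embryonic day 12.5, each made from a pool of mixed-sex embryos. Per the labels, RNA was extracted with the mirVana kit, 10 ng entered each library, a size range of longer RNA was selected, ERCC spike-ins were added, and a SMARTer Ultra Low kit manual is listed among the protocols. Per the text deposited with the tables, each was derived from alignments to the transcriptome of that replicate alone, on mouse build GRCm38 (mm10) with the GENCODE M4 annotation. The series title states that a later deposit supersedes it, and that deposit was not used here. The aligner and the quantifier are not given in the sources used here, and the column names are those RSEM writes.

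The authors' tables give expected counts, which are estimated numbers of reads per feature and need not be whole. They also give TPM, deposited by the authors relative to the total over all features, spike-ins included. The deposited FPKM are scaled by feature length and library size. The deposited posterior mean TPM and the bounds of its interval come from the same tables, and the level of the interval is not given in the sources used here. The deposited transcript tables give each transcript's percent of its gene's TPM. The effective length was the length minus 99 bases. The maximum-likelihood TPM lay inside the deposited interval for 93.4% of genes in replicate 1 and 94.0% in replicate 2, and the posterior mean for 100%, so the intervals belong to the posterior mean.

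The gene tables list 69691 features: 43346 mouse genes, 96 spike-ins, 1 phiX feature and 26248 features with numeric identifiers, whose names the tables do not give. Gene symbols, classes and positions were taken from GENCODE M21 on the same build by gene identifier without its version. This named 42462 genes and left 884 without a name, which held 0.303 ± 0.00473% of TPM. Where a symbol had several identifiers, the one with the higher mean TPM was used, as for Dlx6os1. The listed genes Ahsp, Rmst and Sox2ot were not analysed here because no entry matched. Transcript names and exon positions come from M21, and exons were compared only where both transcripts exist there. The features with numeric identifiers entered no comparison.

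TPM as deposited was the main unit, compared as log2(TPM + 1). A fold on this scale understates the change of low genes. A gene was called detected at 1 TPM. Means and SDs are over the 2 replicates. Intervals and floors, the latter set at 3 counts, cover counting and read assignment error only, since reads without molecular identifiers are not independent molecules. Before the data were examined, 31 gene lists, a further list of all replication-dependent histone genes taken by the cluster names in their symbols, 18 pairs, 24 genes for transcript shares, the comparisons, the tests and the alternatives were fixed. So was the rule for naming genes: members of these lists, by default the 3 highest of each, every member at 1 TPM or more in lists of tissues outside the forebrain, the 10 most abundant nuclear protein-coding genes, and the 5 with the largest log2 ratio in each direction at a mean of 10 TPM or more. Some genes that this rule names are not reported here.

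List medians were compared by a two-sided permutation of membership with 100000 resamples, adjusted by the Benjamini-Hochberg method over 4 comparisons. A pair counted where its members differed in both replicates, in the same direction, by more than the larger difference of either member between replicates. The median log2 ratio of a list between replicates, over members at a mean of 1 TPM or more, was placed among 10000 random lists of equal size drawn from 20 bins of mean expression, and lists of fewer than 5 such members (midbrain, hindbrain and spinal cord, astrocyte, head mesoderm, eye, and RNAs without poly(A) tails) were left out. Expected counts were rounded to whole numbers for edgeR 4.0.16, which gave the biological coefficient of variation after TMM scaling and filterByExpr, and for DESeq2 1.42.0, whose size factors were an alternative. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.

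The procedures were tested on simulated data. Simulated coefficients of variation of 0.05, 0.1 and 0.2 were recovered as 0.0500, 0.0987 and 0.198 over 17370 genes. In 15188 simulated genes, lists of 10 genes changed 1.15-fold fell outside the random range in 4 of 5 cases and lists changed 1.3-fold, 1.5-fold and 2-fold in 5 of 5 cases each, against 15 of 400 unchanged lists. The permutation test called 5.6% of 1000 simulated comparisons without a difference and 98.8% with a difference of 2 SD. These numbers of unchanged lists and comparisons were raised after smaller runs gave unstable rates. Genes were simulated independently of each other, so the rates do not cover lists whose members vary together.

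Alternatives were another pseudocount, FPKM, CPM, posterior means, other thresholds, random lists matched on length, and each replicate alone. After the data were examined, removal of a GC or length trend, random lists from protein-coding genes, genes of 300 bases or more and spike-in scaling of list medians were added.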

Results

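Total RNA was sequenced from forebrain dissected from mouse embryos of the B6NCrl strain at embryonic day 12.5, when the cortical and ganglionic progenitor zones are producing their early neurons. The 2 biological replicates were pools of forebrains of mixed sex, 120 embryos in replicate 1 and 68 in replicate 2. They form 1 group, so the questions the design allows are how abundant each transcript was, how preset groups of genes compared within the libraries, and how closely the pools matched. The expected counts summed to 33711030 in replicate 1 and 34578499 in replicate 2. Values below are means of the replicates in TPM, the abundance of a transcript relative to all others in its library, with the SD over the 2 pools unless another error is named.

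Among nuclear protein-coding genes Tuba1a, the alpha-tubulin of newborn neurons, had the highest level at 6924 ± 238 TPM. It was followed by the embryonic beta-like globin Hbb-y at 5859 ± 1213 TPM, Actb at 5505 ± 122 TPM, the histone Hist1h2ap at 5186 ± 90.8 TPM and the actin-binding peptide gene Tmsb4x at 4986 ± 54.7 TPM. Hba-a2 (4738 ± 970 TPM), the imprinted gene Nnat (4582 ± 335 TPM), Ftl1 (4570 ± 3.83 TPM), Ppia (3825 ± 55.0 TPM) and the microtubule regulator Stmn1 (3816 ± 121 TPM) completed the 10 most abundant. Tuba1a (ENSMUSG00000072235) lies on chromosome 15 from 98949837 to 98953703 and Hbb-y (ENSMUSG00000052187) on chromosome 7 from 103851749 to 103853216, both on the minus strand of GRCm38. The levels of Hist1h2ap, Hba-a2, Ftl1 and Ppia are uncertain because near-identical gene copies or pseudogenes share their reads. Among all gene classes the 7SL RNA genes Rn7s1 and Rn7s2 stood higher, at 8047 and 8047 TPM, but the expected counts were split between these copies, and the short transcripts carry wide deposited intervals (2902 to 13858 TPM for Rn7s1 in replicate 1).

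Nuclear protein-coding genes held 79.9 ± 0.284% of TPM, transcripts of the mitochondrial genome 2.29 ± 0.0151%, long noncoding RNA 2.28 ± 0.161% and annotated pseudogenes 4.00 ± 0.0699%. The pseudogene share includes Gm29216 at 2043 TPM and Gm28437 at 4274 TPM, whose deposited interval in replicate 1 ran from 1529 to 4565 TPM. Reads shared between pseudogenes and near-identical genes can be placed in either. The split between pseudogenes and the other classes, the mitochondrial one included, is therefore uncertain. Synthetic ERCC spike-ins took 8.72 ± 0.669%. Genes annotated as nuclear ribosomal RNA held 0.00787 ± 0.000786%, which leaves out any ribosomal reads counted in entries of other classes. The long noncoding share includes the adjacent entries Gm42418 at 3529 TPM and Gm26917 at 2737 TPM on chromosome 17. The origin of their reads was not tested. Hemoglobin genes together held 1.31% of TPM in replicate 1 and 1.75% in replicate 2. At a threshold of 1 TPM, 15186 genes were detected in replicate 1, 15433 in replicate 2 and 14744 in both, of which 12880 were protein-coding.

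Transcription factors of the telencephalon were expressed throughout, and those of the hindbrain and spinal cord were near or under the detection floor. All 10 telencephalic factors exceeded 1 TPM in both pools, with a median of 52.7 TPM. Lhx2, a selector of cortical identity, stood at 161 TPM in replicate 1 and 185 TPM in replicate 2. The orphan receptor gene Nr2e1 stood at 85.6 ± 0.191 TPM and Nr2f1 at 78.9 ± 15.4 TPM. Emx2 (ENSMUSG00000043969, chromosome 19, 59458372 to 59465357, plus strand), a homeobox gene of the cortical primordium, measured 52.9 ± 6.09 TPM. Of the 14 hindbrain and spinal cord factors, 13 of which are Hox genes, 0 reached 1 TPM and 6 had a count of 0 in both pools. Hoxa3 was the highest at 0.140 ± 0.170 TPM. A floor of 3 counts corresponds to a median of 0.0814 TPM for these genes in replicate 1 and 0.0791 TPM in replicate 2, and with members raised to their floors the telencephalic median was at least 579-fold higher. The medians of log2(TPM + 1) were 5.75 and 0.03, a difference of 5.72 (5.72 in replicate 1 and 5.75 in replicate 2; p = 0.00017 by a two-sided permutation of list membership, adjusted p = 0.00034 over 4 such comparisons). That p-value is across genes, which are not independent replicates.

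Diencephalic genes were also present and midbrain genes were scarce. In the diencephalon list 11 of 12 members passed 1 TPM in both pools, led by Tcf7l2, a Wnt pathway effector of the thalamus, at 177 ± 4.88 TPM, Lhx9 at 33.2 ± 4.31 TPM and Olig3 at 28.4 ± 0.354 TPM. The hypothalamic factors Otp (5.39 ± 0.651 TPM), Sim1 (3.69 ± 0.0495 TPM) and Rax (3.24 ± 0.686 TPM) were lower. Of the 9 midbrain genes only Tal2 passed 1 TPM in both pools, at 3.44 ± 1.31 TPM, while En1 reached 0.855 ± 0.177 TPM and En2 had 0 TPM in both.

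Markers of both the dorsal and the ventral telencephalon were expressed throughout. On the dorsal side Neurog2, a proneural factor of pallial progenitors, measured 135 ± 4.11 TPM, Pax6 90.8 ± 0.969 TPM and Emx1 66.2 ± 10.3 TPM, and all 12 members passed 1 TPM in both pools. On the ventral side all 16 did, led by Dlx1 at 208 ± 53.3 TPM, Dlx2 at 90.1 ± 27.2 TPM and Dlx5 at 69.6 ± 19.7 TPM, homeobox genes of the ganglionic eminences. The list medians of log2(TPM + 1) were 5.24 dorsally and 4.84 ventrally. Their difference of 0.40 did not pass the test (p = 0.618 by a two-sided permutation of list membership, adjusted p = 0.618). It was 0.04 in replicate 1 and 0.78 in replicate 2, so the pools differed from each other by more than the lists did.

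Radial glial genes were far more abundant than genes of mature neurons. Vim, an intermediate filament gene of neural progenitors, measured 914 ± 11.1 TPM, the lipid-binding protein gene Fabp7 876 ± 108 TPM and the Notch effector Hes5 378 ± 2.24 TPM. All 12 radial glial genes passed 1 TPM in both pools, with a median of 61.5 TPM. Of the 10 mature neuron genes 8 did, and their median was 3.69 TPM: Camk2a was highest at 10.8 ± 0.658 TPM, followed by Shank1 at 6.77 ± 0.431 TPM and Syn2 at 5.13 ± 0.615 TPM, and Pvalb stood at 0.0600 TPM in both pools. The difference of the medians of log2(TPM + 1) was 3.74 (3.77 in each pool taken alone; p = 0.00309 by a two-sided permutation of list membership, adjusted p = 0.00412). Some members are expressed outside the named stage, so the lists describe typical use of the genes.

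Cell cycle genes and genes common to all neurons were both abundant. The 15 cell cycle genes had a median of 189 TPM, with Cdk1 at 310 and 314 TPM in the replicates, Top2a at 296 ± 6.24 TPM and Ccnb1 at 286 ± 4.32 TPM. The 15 pan-neuronal genes had a median of 101 TPM, with Tubb3 at 710 ± 38.6 TPM, Map2 at 290 ± 16.2 TPM and the growth cone gene Stmn2 at 210 ± 3.26 TPM. Rbfox3, which encodes the NeuN antigen of older neurons, measured 14.9 ± 1.55 TPM. Genes of Cajal-Retzius cells, the early neurons of the cortical surface, all passed 1 TPM, with Nhlh2 at 37.1 ± 1.54 TPM, Calb2 at 30.2 ± 6.46 TPM, Lhx5 at 21.4 ± 1.74 TPM and Reln at 20.3 ± 1.75 TPM.

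Genes that are used early in development exceeded their later counterparts in most of 18 preset pairs. The earlier member was higher in both pools, by more than the larger of the members' differences between the pools, in 13 pairs. Folds in this paragraph are ratios of mean TPM, whereas the rule used log2(TPM + 1). Fabp7 exceeded the astrocyte gene Aldh1l1 563-fold, the neurofilament gene Nefm exceeded Nefh 91.8-fold, and Map1b exceeded Map1a 53.1-fold. With Nefh at only 0.340 TPM, the log2(TPM + 1) ratio of Nefm to Nefh was 4.71 in replicate 1 and 4.46 in replicate 2. The remaining pairs in this direction, among them Eno1 over Eno2, Ss18 over Ss18l1 and Grin2b over Grin2a, ranged from 2.45-fold for Slc12a2 over Slc12a5 to 125-fold for Eno1, a gene with near-identical copies that share reads. The sodium channel gene Scn3a exceeded Scn1a 12.2-fold. Among globins Hbb-y exceeded the adult gene Hbb-bt 8.59-fold, but adult-type Hba-a1 exceeded embryonic Hba-x 1.88-fold. The later member was also higher for Dpf1 over Phf10, subunits of BAF chromatin remodelling complexes, at 5.03-fold, and for the splicing regulator Ptbp2 over Ptbp1 at 1.27-fold. Actl6a, the progenitor counterpart of neuronal Actl6b in the same complexes, was 2.98-fold higher than Actl6b. The remaining pairs did not meet the rule. The log2 ratio of Camk2b to Camk2a was -0.11 in replicate 1 and -0.29 in replicate 2, against a difference between the pools of 0.11, and that of Dlg3 to Dlg4 was 0.28 and -0.26.

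Transcripts that mark blood, vessels, meninges and immune cells were present. Erythroid genes were the most abundant of these lists, with 12 of 13 members above 1 TPM in both pools and a median of 312 TPM. Besides Hbb-y and Hba-a2, Hba-a1 measured 2150 ± 368 TPM, Hba-x 1142 ± 274 TPM, Hbb-bt 682 ± 135 TPM, Hbb-bh1 432 ± 116 TPM and Hbb-bs 312 ± 62.9 TPM. The near-identical copies Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, share reads. The heme synthesis gene Alas2 stood at 27.0 ± 6.75 TPM and Slc4a1 at 19.3 ± 2.70 TPM, while Epb42 and Klf1 measured 3.42 and 2.43 TPM. All 12 genes of meninges and mesenchyme passed 1 TPM, and their median was 22.3 TPM. The collagen genes Col3a1 (307 and 339 TPM in the replicates), Col1a1 (195 ± 35.1 TPM) and Col1a2 (141 ± 28.3 TPM), with Crabp2 (202 ± 0.552 TPM) and Lum (78.5 ± 14.2 TPM), were the highest, followed by Prrx1, Dcn, Pdgfra, Postn, Twist1, Foxc1 and Foxc2, which ranged from 24.3 down to 3.25 TPM. All 11 endothelial genes passed, with a median of 12.8 TPM, led by Egfl7 at 42.4 ± 4.16 TPM, Kdr at 20.5 ± 0.933 TPM and Cldn5 at 20.3 ± 0.205 TPM. Mural cell genes passed in 9 of 10 cases (median 4.41 TPM), with Acta2 at 30.4 ± 13.0 TPM, Vtn at 28.9 ± 2.45 TPM and Notch3 at 18.3 ± 0.997 TPM. Microglia and macrophage genes passed in 12 of 13 cases (median 6.47 TPM), with C1qb at 14.3 ± 1.68 TPM and Fcer1g at 11.5 ± 1.58 TPM.

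The roof plate and choroid plexus list had 11 of 12 members above 1 TPM in both pools and a median of 5.84 TPM. Ttr, the transthyretin gene of choroid epithelium, was highest at 63.7 ± 29.3 TPM, followed by Msx1 at 44.6 ± 16.2 TPM and Msx2 at 12.1 ± 5.73 TPM. Surface ectoderm genes passed in 9 of 10 cases with a median of 4.42 TPM: Epcam at 13.7 ± 1.48 TPM, Krt8 at 10.4 ± 2.09 TPM and Krt18 at 9.70 ± 2.47 TPM were followed by Krt14, Perp, Krt5, Krt15, Cdh1 and Grhl3 at 5.02 to 1.95 TPM, and Trp63, at 1.14 TPM on average, stayed under 1 TPM in replicate 1. Head muscle and cartilage genes passed in 2 of 10 cases, Col9a1 at 9.17 ± 3.15 TPM and Actc1 at 3.78 ± 2.17 TPM, while Acta1 measured 0.780 TPM in replicate 1 and 2.04 TPM in replicate 2. Of the 8 eye and pigment cell genes only Dct passed in both pools, at 7.13 ± 0.601 TPM. Pmel measured 0.710 TPM in replicate 1 and 3.61 TPM in replicate 2, Cryba1 1.10 and 0.910 TPM, and the lens gene Cryaa had 0 TPM. Of the glial lists, 5 of 7 oligodendrocyte lineage genes passed (Olig2 at 20.9 ± 4.36 TPM, Mbp at 12.9 ± 2.62 TPM, Olig1 at 8.95 ± 1.12 TPM), as did 4 of 7 astrocyte genes (Gja1 at 96.9 ± 7.87 TPM, Aldoc at 24.2 ± 2.57 TPM, Slc1a2 at 10.3 ± 0.601 TPM), while Gfap measured 0.02 TPM in replicate 1 and 0.08 TPM in replicate 2.

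**Figure D1:**
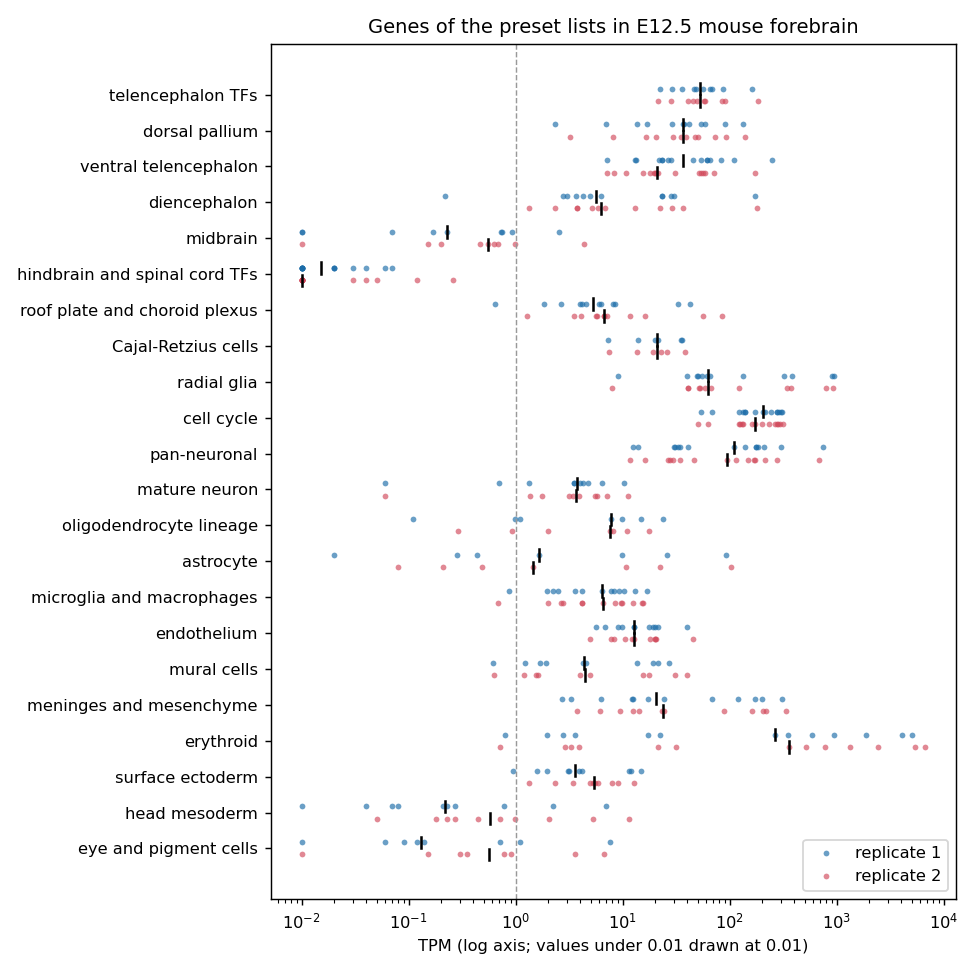
TPM of each gene (horizontal log axis, 1 point per gene, blue for replicate 1 and red for replicate 2) in 22 preset lists, with a black tick at each list's median per replicate and a dashed line at 1 TPM. Telencephalic factors centre on 52.7 TPM, whereas the hindbrain and spinal cord factors all lie left of the 1 TPM line.

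Signalling and other gene groups were measured alongside. All 18 patterning ligands, receptors and effectors passed 1 TPM in both pools, with Wnt7b at 93.5 ± 11.1 TPM, Sfrp1 at 91.6 ± 4.57 TPM and Fgfr3 at 78.9 ± 15.7 TPM highest and Shh lowest at 2.95 ± 0.834 TPM. All 19 imprinted genes passed, with Nnat followed by Mest at 736 ± 85.6 TPM and Meg3 at 534 ± 66.2 TPM. Xist measured 17.4 TPM in replicate 1 and 24.6 TPM in replicate 2, and the Y-linked genes Eif2s3y 36.5 ± 6.24 TPM, Ddx3y 19.7 ± 0.559 TPM, Kdm5d 17.5 ± 1.52 TPM and Uty 14.6 ± 0.460 TPM, in pools the labels describe as containing both sexes. Immediate early genes that respond to handling were mostly low: Fos stood at 0.795 ± 0.191 TPM and Egr1 at 1.76 ± 0.0778 TPM, against 108 ± 4.02 TPM for Btg2, 85.6 ± 2.88 TPM for Jun and 47.8 ± 5.12 TPM for Ier2. Hypoxia and glycolysis genes passed in 9 of 10 cases, led by Ldha at 861 ± 36.2 TPM, Pgk1 at 291 ± 0.0778 TPM and Slc2a1 at 95.3 ± 1.20 TPM, and Vegfa was at 3.38 ± 0.0778 TPM. Among heat shock genes the constitutive Hspa8 reached 2326 ± 84.6 TPM, Hsph1 89.8 ± 4.67 TPM and Dnajb1 71.3 ± 3.21 TPM, while inducible Hspa1a stood at 1.75 ± 0.177 TPM. Of 9 neural long noncoding RNAs analysed, Malat1 was highest at 5768 ± 1019 TPM, then Pantr1 at 373 ± 64.7 TPM and Dlx1as at 84.1 ± 26.9 TPM. The Malat1 level is uncertain. In replicate 1 it rests on 43503 expected counts for 5047 TPM, close to the 39533 for 5122 TPM of the short gene Hist1h2ap. Its TPM was therefore computed at a short effective length, although the gene spans 5795690 to 5802672 on chromosome 19. The entry Gm37376 (2105 TPM) lies within it on the opposite strand. Antisense and host-gene reads of Dlx1as and Malat1 cannot be separated here because no source states that counting used strand.

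The median gene among the listed histone variants with poly(A) tails was more abundant than the median replication-dependent histone gene, whose transcripts end in a stem-loop. The 7 polyadenylated variants had a median of 724 TPM, with H3f3a at 2911 ± 91.9 TPM, H2afz at 2506 ± 74.3 TPM and H3f3b at 1932 ± 46.6 TPM. The 66 replication-dependent genes had a median of 9.29 TPM, and 51 of them passed 1 TPM in both pools. Hist1h2ap was the highest at 5186 TPM, above H3f3a, followed by Hist1h4d at 403 TPM and Hist1h2ae at 223 TPM. The medians are per gene and do not compare the totals of the classes. In expected counts, which are not divided by length, the variants summed to 221662 in replicate 1 and 223507 in replicate 2. The replication-dependent genes summed to 57404 and 62269. The difference of the medians of log2(TPM + 1) was 6.14 (6.36 in replicate 1 and 6.01 in replicate 2; p = 3e-05 by a two-sided permutation of list membership, adjusted p = 0.00012). Paralogous histone genes share reads, so the split among them is uncertain. Short RNAs without poly(A) tails were also counted: Rn7sk, the RNA of the 7SK complex, measured 250 ± 55.1 TPM, Rpph1 71.8 ± 16.4 TPM, Rmrp 4.03 ± 2.02 TPM and Terc 0.61 TPM in replicate 1 and 0.59 TPM in replicate 2.

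Transcript shares were compared for genes with known alternative transcripts. Pkm-201 carried 88.8 ± 0.601% of Pkm TPM and Pkm-202 11.2 ± 0.601%. In the annotation used for positions the former contains a 167-base exon at chromosome 9, 59675568 to 59675734, where the latter has a 167-base exon at 59675029 to 59675195, and the downstream exon is the one found in the PKM2 enzyme. For Snap25, which encodes a presynaptic fusion protein, Snap25-201 carried 70.3 ± 1.26% and Snap25-202 25.7 ± 1.94%. Cdc42-202, with a last exon at chromosome 4, 137319696 to 137321192, carried 82.5 ± 0.771%, and Cdc42-201, whose alternative last exon spans 137321762 to 137322619, carried 17.5 ± 0.771%. Mapt-205, which includes a 54-base exon at chromosome 11, 104307881 to 104307934, carried 51.5 ± 2.49% of the tau gene's TPM, and Mapt-204, which lacks it, 33.0 ± 1.12%. Their annotated last exons also differ, with 464 bases in Mapt-205 and 4119 in Mapt-204. The shares therefore do not measure use of the 54-base exon alone. Clta-206 carried 56.7% in replicate 1 and 58.4% in replicate 2, and Clta-204, which adds a 54-base exon at chromosome 4, 44030215 to 44030268, carried 33.0 ± 0.856%. Ncam1-204 carried 81.7 ± 0.0636% and Ncam1-205 15.9 ± 0.240%. For Dcx, a microtubule protein gene of migrating neurons, the leading transcript differed between the pools: Dcx-203 carried 44.2% in replicate 1 and 32.3% in replicate 2, and Dcx-201 38.1% and 46.6%. Among the 24 preset genes, leaving out Ptbp2 and App, which have 1 transcript listed each, the leading transcript was the same in both pools for all but Dcx and Fgfr2. Across 7990 genes with at least 2 transcripts and 5 TPM, the same transcript led in both pools for 7409, or 92.7%, and the leading transcript had a median share of 68.6% in replicate 1 and 67.9% in replicate 2. Pkm-202 has a different length in the release used for counting, so its outer exon ends are not those of the counted transcript.

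**Figure D2:**
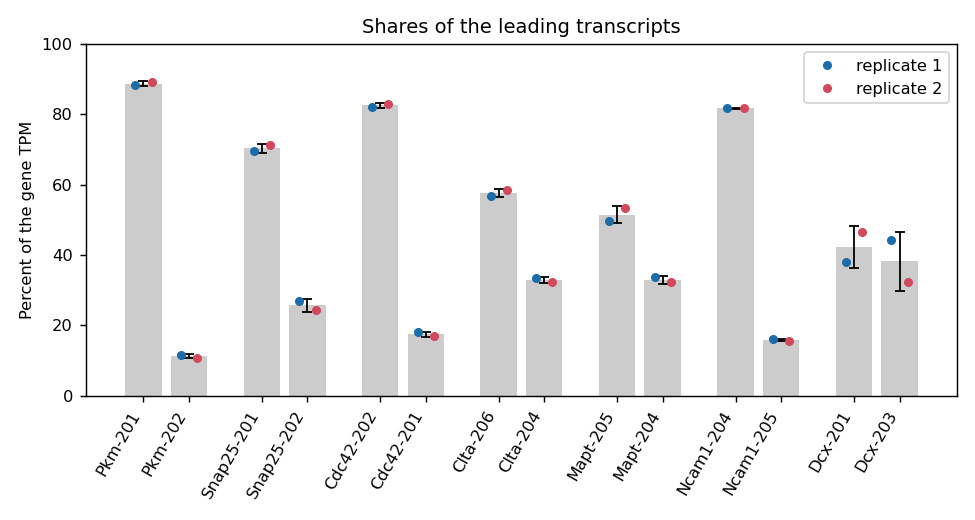
Percent of gene TPM (vertical axis, from 0) carried by the 2 leading transcripts of 7 genes; bars are means of 2 replicates, error bars the SD, and points the replicates. Pkm-201 and Cdc42-202 lie at 88.8% and 82.5%, while the Dcx transcripts exchange rank between replicates.

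The pools agreed closely for most genes. Across 14744 genes at 1 TPM or more in both, log2(TPM + 1) had a Pearson correlation of 0.994 and a Spearman correlation of 0.993, computed across genes, which are not independent replicates. The log2 ratio had an SD of 0.22 and 71 genes differed more than 2-fold, 29 higher in replicate 1 and 42 higher in replicate 2. The split was 9 and 16 in CPM with TMM factors, and 19 and 74 with scaling by the spike-in total. Of those 71 genes, 37 had an effective length under 300 bases and 41 had fewer than 30 counts in a replicate. To check whether 1 library had been deposited under both labels, a chi-square of the rounded counts was computed over 18941 genes. It was 7.91 per degree of freedom, where a library split at random would give about 1, and the pools were counted as 2 replicates. The common biological coefficient of variation estimated by edgeR was 8.11% over 16772 genes. It describes the spread between the pools, library preparation included, and does not measure variation between single embryos. The spike-ins had a Pearson correlation of 0.999 and a Spearman correlation of 0.989 across the 96 sequences, of which 83 had reads in replicate 1 and 89 in replicate 2. Scaling by the spike-in total moved the median log2 ratio of all genes from -0.01 to -0.15, and comparisons between the pools below are relative to other genes.

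Among nuclear protein-coding genes at a mean of 10 TPM or more, the largest ratios named individual regulators and markers. Higher in replicate 2 were Cop1, an E3 ubiquitin ligase gene (84.5 against 27.2 TPM, 3.03-fold on the log2(TPM + 1) scale), the Polycomb gene Phc2 (121 against 45.9 TPM), Crls1 (21.2 against 8.78 TPM), H1fx (80.0 against 39.0 TPM) and Ttr (84.4 against 42.9 TPM). Higher in replicate 1 were Lhx8 (45.4 against 20.6 TPM, 2.15-fold on the same scale), Etv1 (35.2 against 18.3 TPM), Nkx2-1 (54.3 against 30.7 TPM) and Spry2 (14.9 against 8.23 TPM). The deposited TPM intervals did not overlap between the pools for any of these genes. Lhx8 (ENSMUSG00000096225, chromosome 3, 154306294 to 154330659, minus strand) and Nkx2-1 (ENSMUSG00000001496, chromosome 12, 56531958 to 56536908, minus strand) encode transcription factors of the ventral forebrain. Each pool is a single library, so these differences have no replicate check.

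Several preset lists lay higher in either pool as a group. The ventral telencephalon list was higher in replicate 1 in 16 of 16 members, with a median log2 ratio of 0.41. Examples are Dlx1 at 246 against 171 TPM, Dlx2 at 109 against 70.8 TPM and Gsx2 at 26.5 against 15.4 TPM. The dorsal pallium list was higher in replicate 2 in 10 of 12 members, with a median of -0.13 that became -0.08 with the GC trend removed, as for Emx1 at 73.5 against 58.9 TPM. Also higher in replicate 2 were the roof plate and choroid plexus list (10 of 11 members, median -0.49), the erythroid list (11 of 12, median -0.41), the meninges and mesenchyme list (12 of 12, median -0.36) and the surface ectoderm list (7 of 10, median -0.31). For these, Ttr, Hbb-y (6716 against 5001 TPM), Col1a1 (220 against 171 TPM) and Krt15 (4.94 against 1.98 TPM) are examples. Replication-dependent histones (43 of 54 higher in replicate 2, median -0.18, which became -0.11 with either the GC or the length trend removed) and Xist with the Y-linked genes (4 of 5, median -0.17) lay on the same side. Neural long noncoding RNAs had a median of -0.14 but a mean of 0.05, which differ in sign. Pan-neuronal genes (12 of 15 higher in replicate 1, median 0.11), cell cycle genes (13 of 15, median 0.06) and the oligodendrocyte lineage (4 of 5, median 0.23) were higher in replicate 1. Scaling by the spike-ins shifts all genes together, which by itself turns the pan-neuronal and cell cycle medians to -0.04 and -0.09, and relative to the median of all genes they were then 0.11 and 0.06.

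These 12 of 26 lists had medians in the lowest or highest 2.5% of 10000 random lists of equal size matched on mean expression. If genes varied independently, 1.3 would be expected by chance. Members of a list can vary together, which the random lists do not reproduce, so 1.3 may be too low. The comparison describes these libraries and is not a test between conditions. The percentile was 100 for the ventral list and 0 for the erythroid, meninges and roof plate lists, while the sex-linked list at 2.48 lay at the limit. The cell cycle, oligodendrocyte and sex-linked lists each moved inside the range under an alternative, with matching on length, no filter on low values and posterior means, respectively. The endothelial (-0.02), radial glial (0.00), Cajal-Retzius (-0.01), mural (0.02), diencephalon (-0.02), telencephalon (0.01), signalling (-0.01) and hypoxia (-0.03) medians were close to 0. The microglia and macrophage (-0.08), mature neuron (-0.11), imprinted (0.04), immediate early (0.07), heat shock (0.09) and polyadenylated histone (0.06) medians also lay inside the range. Mean and median differed in sign for the telencephalon (mean -0.05), Cajal-Retzius (mean 0.06), mural (mean -0.10), imprinted and heat shock lists.

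**Figure D3:**
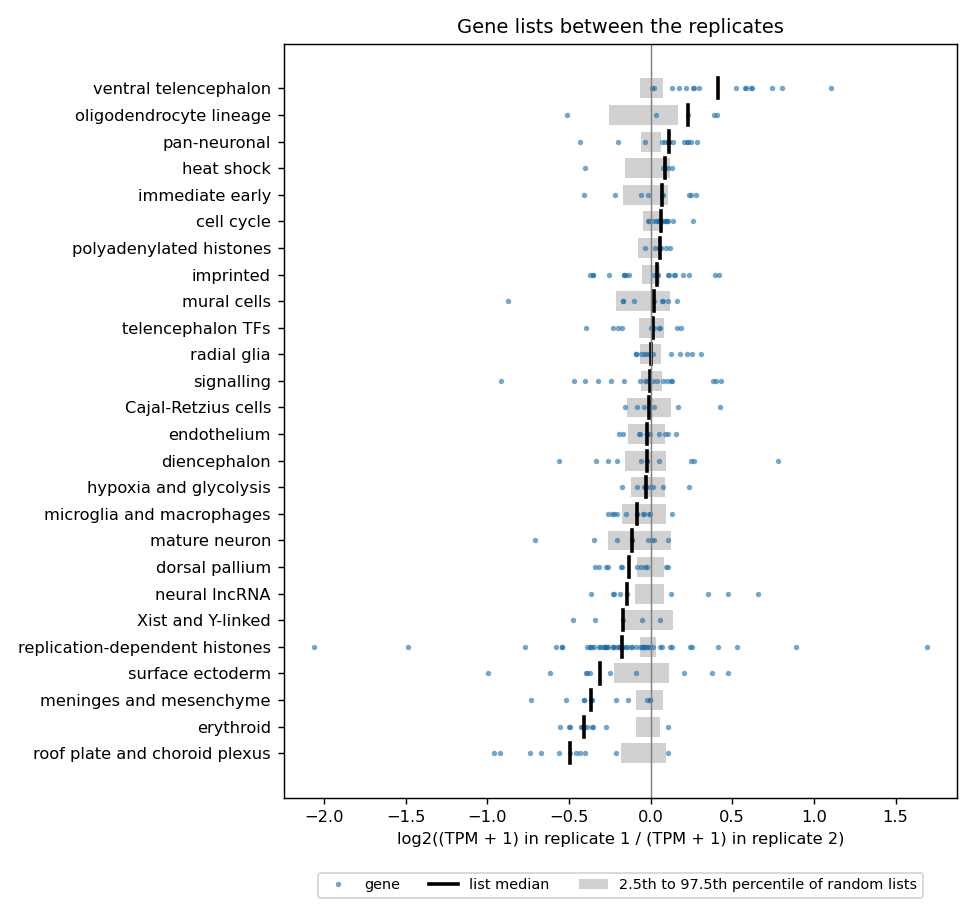
Log2 ratio of TPM + 1 in replicate 1 to that in replicate 2 (horizontal axis) for genes of 26 preset lists at a mean of 1 TPM or more; points are genes, black ticks list medians and grey bars the range that leaves 2.5% of random lists on either side. The ventral telencephalon median of 0.41 and the roof plate and choroid plexus median of -0.49 lie farthest to either side.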

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

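The test of poly(A) priming was set before its result was seen, as were the tests on additional lists of mesenchyme, erythroid and ganglionic eminence genes, which were themselves written after the preset lists had been compared, the ventral progenitor list only after the medial and lateral eminence lists had given no upward shift; the tests of GC and length trends, of interval overlap and of the endothelial list were chosen after the patterns were seen. The requirement that a difference exceed the SD over a list's members was also added after the earliest values were seen. The features with numeric identifiers, which entered no comparison, held expected counts of 19.7 in replicate 1 and 32 in replicate 2, above the floor of 3 counts. These counts fell in 8 and 9 of 26248 features, whose median length is 73 bases, and only 63 features are longer than the 99 bases subtracted for the effective length. No explanation of them was tested.

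The ventral telencephalon list was higher in replicate 1 in 16 of 16 members. With the length trend removed its median log2 ratio was 0.41, with the GC trend removed 0.42, and in 12 of 16 members the deposited intervals did not overlap, which argues against those trends and against counting and read assignment error as the whole cause. A larger share of the ganglionic eminences in replicate 1 may be proposed, but additional lists of genes of the medial eminence (8 genes, median -0.055, percentile 27.2), the lateral eminence (7 genes, median -0.21, percentile 0.84) and ventral progenitors (6 genes, median -0.26, percentile 2.51) were not higher in that pool, against a median of 0.41 for the preset list and 0.26, in 13 of 13 members, without Nkx2-1, Lhx6 and Lhx8. What stays open is a difference limited to the homeobox genes of the list, or a difference in dissection or stage between pools, none of which was tested.

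Erythroid, mesenchymal and roof plate lists were higher in replicate 2. The erythroid median was -0.35 with the length trend removed, so that trend does not account for it. A lower share of neural cells would raise every other cell type alike, yet the endothelial median was -0.019 (SE 0.0332 over 11 members) against -0.36 for meninges and mesenchyme. Additional lists with no preset members moved with the pattern, with medians of -0.26 for 12 mesenchyme genes and -0.33 for 10 erythroid genes, at percentiles 0.02 and 0.16, consistent with more attached mesenchyme and more blood in replicate 2. The design has no group that gives a biological explanation, and the roof plate list had no such additional list.

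The difference between the per-gene medians of polyadenylated and replication-dependent histones could come from cDNA priming at poly(A) tails. The median of the replication-dependent genes was 9.29 TPM, between the 5 TPM under which priming was predicted and the 20 TPM at which it was not, so priming and a real difference in abundance cannot be told apart. The cell cycle list had a median of 189 TPM. Reads shared among histone paralogs add to this uncertainty. A per-gene median also does not give the total of the class, in which Hist1h2ap alone stood at 5186 TPM.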

How the results depend on the processing

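The removal of GC and length trends, random lists from protein-coding genes and the length limit were chosen after the data were examined. In 62 alternatives a main result kept its direction and side of the threshold, or, where it is a count or the coefficient of variation, stayed within 1.5 times its main value, or, for a share of the library, within its SD, and in 9 it moved by more. Within 1.5 times, the 14744 genes detected became 19725 at 0.1 TPM, 11017 at 5 TPM, 18383 with posterior means and 13542 in FPKM, and the 277 list members at 1 TPM or more in both pools became 306 at 0.1 TPM and 220 at 5 TPM. Lists apart between the pools numbered 11 to 13, against 12. Counted in reads instead of TPM, nuclear protein-coding genes held 91.7% and spike-ins 3.53%, since counts are not divided by length. The 71 genes beyond 2-fold became 54 in FPKM, 93 with spike-in scaling, 25 in CPM with TMM factors, 41 with posterior means, 143 with a pseudocount of 0.1, 381 with no filter on low values, 9 at 10 TPM or more in both pools and 34 at 300 bases or more. The last 3 follow from the genes included. Over the same 14744 genes, the smaller pseudocount compresses the ratios of low genes less, and spike-in scaling shifts all genes together. The cause of the changes in FPKM, in CPM and with posterior means was not tested. At a gene level of 20 TPM or more, 4861 genes had the same leading transcript in both pools, since fewer genes were included. Of the other alternatives, 234 left a list on its side of the limits or the Pearson correlation between the pools at 0.992 to 0.996, 3 brought a list inside them and 3 placed a list outside. With no filter on low values, the head muscle and cartilage list, otherwise too small to compare, also lay outside, with a median of -0.39 and 8 of 10 members higher in replicate 2. Among lists that stayed outside, the cell cycle median was 0.04 in FPKM, the dorsal pallium median became -0.08 with the GC trend removed, at percentile 1.82, and that of replication-dependent histones -0.11 with the GC or length trend removed. The cell cycle list lay inside with random lists matched on length, the oligodendrocyte list with no filter and the sex-linked list with posterior means, while the imprinted list lay outside with random lists from protein-coding genes and the polyadenylated histones with matching on length or the length trend removed. No paired analysis was possible because there is 1 group. Depth limits the lowest genes, where 3 counts are worth about 0.0814 TPM for the hindbrain list.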

Other observations

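Genes of the ganglionic eminences outside the preset lists were measured in both pools, and their choice followed inspection of the ventral list. Lmo1, a LIM-only gene, stood at 61.7 ± 8.75 TPM, Foxp1, a factor of striatal neurons, at 61.9 ± 4.16 TPM, and the interneuron peptide genes Sst and Npy at 44.7 ± 1.54 and 21.1 ± 0.757 TPM (SD, n = 2). The striatal genes Foxp2, Penk and Tac1 measured 25.8 ± 0.806, 16.1 ± 2.55 and 13.4 ± 2.21 TPM. Drd2, Ikzf1 and Gbx1 lay under 1 TPM, at 0.715, 0.775 and 0.940 TPM. Rarb, Zfp503 and Penk were higher in replicate 2, at 11.9 against 9.40, 11.4 against 8.97 and 17.9 against 14.3 TPM, opposite in direction to the Dlx genes, while Tac1 was higher in replicate 1, at 15.0 against 11.9 TPM.

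Pallial and mesenchymal genes chosen in the same way included Sox5 at 72.7 ± 8.89 TPM, Zbtb20 at 63.7 ± 4.82 TPM and Neurod2 at 16.6 ± 0.453 TPM. Dmrt3, a gene of the medial pallium, was 15.6 TPM in replicate 2 and 9.68 TPM in replicate 1, and the added pallial list had a median log2 ratio of -0.04 (9 genes, percentile 25.2), for which no prediction was written. Fbln1 (87.5 ± 6.70 TPM) and Cxcl12 (49.3 ± 4.24 TPM) were the most abundant of the added mesenchyme genes.

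The test of FGF response genes was set before their values were seen, and the test of small nucleolar RNAs after. A stronger FGF response in replicate 1 might raise Etv1, Etv5 and Spry2 together, but 8 other response genes had a median log2 ratio of 0.046, at percentile 84.7, with Etv4 at 5.73 against 3.85 TPM and Spred1 at 11.1 against 16.1 TPM, which leaves the hypothesis open. A larger share of RNA without poly(A) tails in replicate 2 might raise the replication-dependent histones there. The 114 small nucleolar and Cajal body RNAs had a median log2 ratio of 0.030, at percentile 99.9, with a wide SD of 1.58 over members. Of them, 58 were higher in replicate 1 and 55 in replicate 2. The libraries were selected for longer RNA, and these RNAs together with small nuclear RNAs and microRNAs held only 0.00560% of expected counts. The list therefore cannot decide the question. Of the 4 preset RNAs without poly(A) tails, Rn7sk (211 and 289 TPM) and Rpph1 (60.2 and 83.4 TPM) were higher in replicate 2 with deposited intervals that did not overlap, which goes with the hypothesis, but these are too few to test as a list. In all, 9 additional lists were compared between the pools after the preset lists had been seen, the preset ventral list without Nkx2-1, Lhx6 and Lhx8 among them.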
